A study of Marchantia polymorpha with 9 samples.

How the data were processed

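Gene expression was measured by RNA sequencing of whole thalli, the flat plant body, of the liverwort Marchantia polymorpha. Per the labels, all plants were male and of the Cambridge strain. They were raised from gemmae, small vegetative propagules, on agar with half-strength Gamborg's B5 medium at 22 °C with 16 h of white light and 8 h of darkness, and were harvested at 10 days. RNA was extracted from about 100 mg of fresh tissue per sample with a plant RNA kit and treated with DNase. There were 9 samples, 3 each of the genotypes labelled WT, OX and KO. The labels do not spell these out, and they are read here as wild type, overexpression and knockout, as is usual in the field. They name no gene and no individual line. The library names of all 9 samples carry the same flow cell and lane, so no sequencing batch separates the genotypes.

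The values analysed are the raw counts per gene that the authors deposited, 1 column per sample and 19287 gene IDs. The IDs belong to version 3.1 of the Marchantia polymorpha gene models, per the file headers and row names. STAR 2.5.1b and featureCounts 1.5 are named in the submitters' processing notes. Their settings, the use of strand and the genome build are not given in the sources used here. Reads from near-identical gene copies or overlapping genes may therefore have been split or dropped in a way that was not checked here. All 173583 values in the deposited count table were even numbers, so 1 read pair appears to have been counted as 2. The test was run on the counts as deposited, and a run on halved counts was added after seeing the data. Limits of detection and counting intervals were computed from read pairs, which are the counts divided by 2. No column of other samples was present (0 columns).

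Library totals ranged from 44802998 to 57696744 counts, or 22401499 to 28848372 pairs. At this depth, 3 pairs in a library, the limit that a count of 0 allows, correspond to between 0.104 and 0.134 CPM, counts scaled to a common library size. These limits and the 95% exact binomial intervals on ratios of summed pairs cover counting error only, because reads without molecular identifiers are not independent molecules. Chi-square tests of the counts of replicate pairs gave 6.60 to 18.0 per degree of freedom, far above sampling noise, so no 2 libraries were treated as duplicates.

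Counts were modelled with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the genotypes as groups, which left 14813 of 19287 genes; 760 had no count in any library. Libraries were scaled by TMM factors, which ranged from 0.958 to 1.04. A quasi-likelihood model with 1 mean per genotype was fitted to all 9 libraries together, so that the genotypes share one estimate of the spread. The F tests of OX against WT, KO against WT, OX against KO, and of any difference among the 3 genotypes were adjusted by Benjamini and Hochberg's method over all genes tested, with a threshold of 0.05. Every adjusted p-value given below comes from these tests unless another tool is named. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries, and standard errors of log2 fold changes were derived from the F statistics. The series design states 3 biological replicates for each line, which gives 1 line per genotype with these samples. The p-values thus cover the spread between plants of a line, and a difference between genotypes cannot be separated from a difference between lines.

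The file does not pair the gene IDs with names. The name table used here, of assembly MpTak2_v7.1 with 18391 rows, uses other identifiers, and 0 of the file's IDs matched it. No coordinates or gene functions are therefore given. The row of the MYB gene that the series is about was not identified, because no source used here ties its name to an ID. Whether it is among the IDs called or named below is therefore not known. For this case the rule set before the data were examined names, for each pairwise comparison, the 2 IDs with the largest rise and the 2 with the largest fall. They were taken from genes past the threshold whose libraries did not overlap between the genotypes and whose mean was at least 5 CPM in the higher genotype. Before the data were examined, 33 gene lists were also fixed, for cuticle and wax synthesis, cell walls, phenylpropanoids, photosynthesis, stress, hormones and cell types among others. With no names or sequences, 0 of the lists defined by product names and 0 of those defined by protein motifs could be tested. Of the lists defined by IDs, the organelle list matched 0 genes, and the list of Y-chromosome IDs had 113 genes, 34 of them tested. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, with camera and an estimated correlation, and with fry.

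Comparisons of OX and of KO with WT share the WT libraries. The overlap of their calls is given beside that of independent lists of the same sizes and beside 20 simulations in which all 9 libraries came from unchanged groups. With 3 control libraries, the controls could not be split into 2 parts of at least 2 libraries. The procedure was tested on simulated counts with 200 genes changed by known folds. The spread used for the draws was estimated on the deposited counts, in which pairs count 2-fold, and the draws were then doubled. Part of the counting noise thus entered again, mainly at low counts, so the recovered shares may be too low. The 20 simulations of unchanged groups were drawn in the same way. Of the genes changed 2-fold, 79.1% were recovered for OX against WT (14588 genes tested), 83.6% for KO against WT (14593 genes) and 77.6% for OX against KO (14574 genes). Of those changed 1.5-fold, 53.7%, 67.2% and 68.7% were recovered, in the same order. False calls made up 5.10%, 8.94% and 6.55% of all calls, so the adjusted p-values held the aimed share of 0.05 only roughly. Alternatives were other scalings, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, fits on 2 genotypes only, replicate number as a block, each library left out, and a 2-fold minimum. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The random seeds of the simulated changes and of the matched gene sets were changed once after their results were seen, for a reason of formatting (2 seeds equalled printed values), and all values given are from the second draw.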

Results

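The series asks how a land plant MYB transcription factor lineage related to MIXTA, a regulator of epidermal cell shape in flowering plants, bears on the plant cuticle. Transcript levels were compared among thalli of 3 genotypes labelled WT, OX and KO, with 3 libraries each. Library totals were 57266826, 44802998 and 57367676 counts for WT replicates 1 to 3. They were 53250950, 57696744 and 57153860 counts for OX, and 57372362, 57683784 and 57478396 counts for KO. The 10 most abundant genes took 6.26% to 7.43% of the counts of a library.

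The 3 genotypes formed 3 separate clusters of libraries. The first principal component, with 52.0% of the variance, placed the OX libraries between 45.0 and 58.2, the WT libraries between -22.5 and -17.8, and the KO libraries between -33.7 and -32.5. The second component, with 21.7% of the variance, separated WT from KO. Across the 14813 genes tested, log2 CPM values correlated at 0.990 to 0.993 between libraries of a genotype. Correlations were 0.978 to 0.983 between WT and KO, 0.965 to 0.976 between WT and OX and 0.962 to 0.970 between OX and KO. In all, 5453 genes (36.8%) differed between any of the 3 genotypes.

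**Figure D1:**
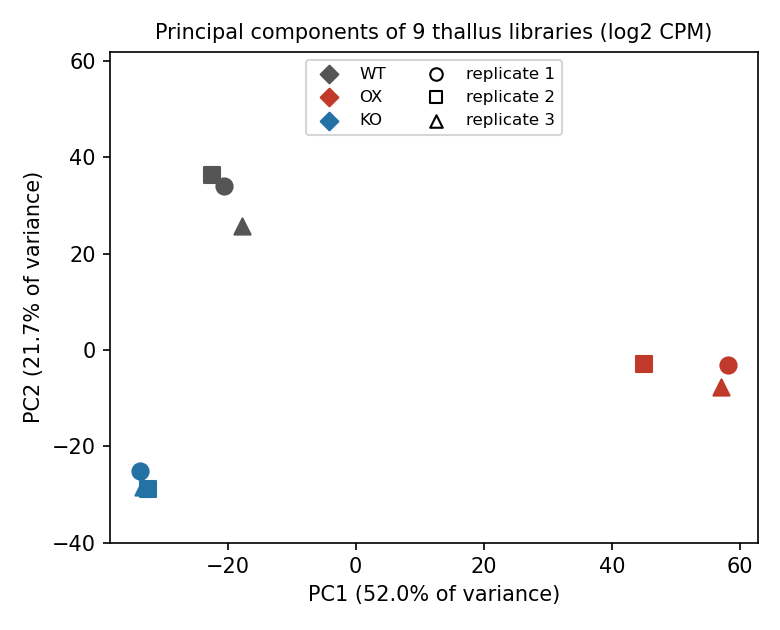
Scores of the 9 libraries on the first 2 principal components of log2 CPM over 14813 genes, with the share of variance on each axis. Colours mark the genotypes and symbols the replicate numbers; the first component holds 52.0% of the variance and sets the OX libraries apart, and the second (21.7%) separates WT from KO.

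The comparison of OX with WT asks which transcripts differ when the genotype labelled OX is set against its wild type. The rises and falls named in this and the next comparisons are the largest among called genes with at least 5 CPM in the higher genotype and no overlap between its libraries and those of the other. The largest rise was that of Mapoly0023s0165, which had 944 ± 48.1 CPM in OX and 10.5 ± 1.26 CPM in WT (n = 3 libraries each), a log2 fold change of 6.49 ± 0.12 (SE) with an adjusted p of 1.05e-09. Its level in KO was 8.23 ± 1.11 CPM, which did not pass the test against WT (log2 fold change -0.35, adjusted p = 0.0548). The second largest rise was that of Mapoly0005s0110, from 0.135 ± 0.094 to 5.72 ± 0.24 CPM (log2 fold change 5.35 ± 0.26, adjusted p = 4.19e-07). The largest falls were those of Mapoly0196s0014 and Mapoly0196s0012, which carry the same scaffold number in their IDs. Mapoly0196s0014 fell from 5.44 ± 0.52 CPM in WT to 1 read pair in the 3 OX libraries together, against 431 pairs in WT. The ratio of the sums was 454, with a 95% counting interval of 81.1 to 17990 (adjusted p = 2.60e-07). Mapoly0196s0012 fell from 6.58 ± 0.83 to 0.0445 ± 0.077 CPM (log2 fold change -7.09 ± 0.50, adjusted p = 4.69e-06), and its 4 pairs in OX all came from replicate 2. In KO these genes had 3.92 ± 0.53 and 4.04 ± 0.71 CPM, and neither passed the test against WT (adjusted p = 0.125 and 0.146).

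Between OX and WT, 3667 of the 14813 genes (24.8%) changed, 1554 of them higher and 2113 lower in OX. Most changes were small, and 2747 of the changed genes differed by less than 2-fold. Among changes of at least 2-fold, 228 genes rose and 692 fell. At 16-fold or more, 11 genes rose and 106 fell. The genes that fell at least 4-fold had a median WT level of 1.79 CPM and those that rose as much 0.169 CPM, against 19.5 CPM for all genes tested. Part of the gap between falls and rises follows from the choice, since a gene very low in WT has little room to fall. Of the 692 falls of at least 2-fold, 337 were among the 2963 genes of lowest abundance and 259 among the next 2962, where mean levels were at most 11.8 CPM. Of the 228 rises of this size, 117 and 76 were in the same groups of genes. The libraries of OX and WT did not overlap in 40.2% of genes, against 10% by chance.

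The balance of rises and falls over all changed genes depended on the scaling. With TMM factors 42.4% of the changed genes were higher in OX, and with library size alone 57.2% were. The latter scaling moved the median log2 fold change of all genes by less than 0.1, from 0.010 to 0.061. At 2-fold or more, falls outnumbered rises with library size alone as well (656 against 263).

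**Figure D2:**
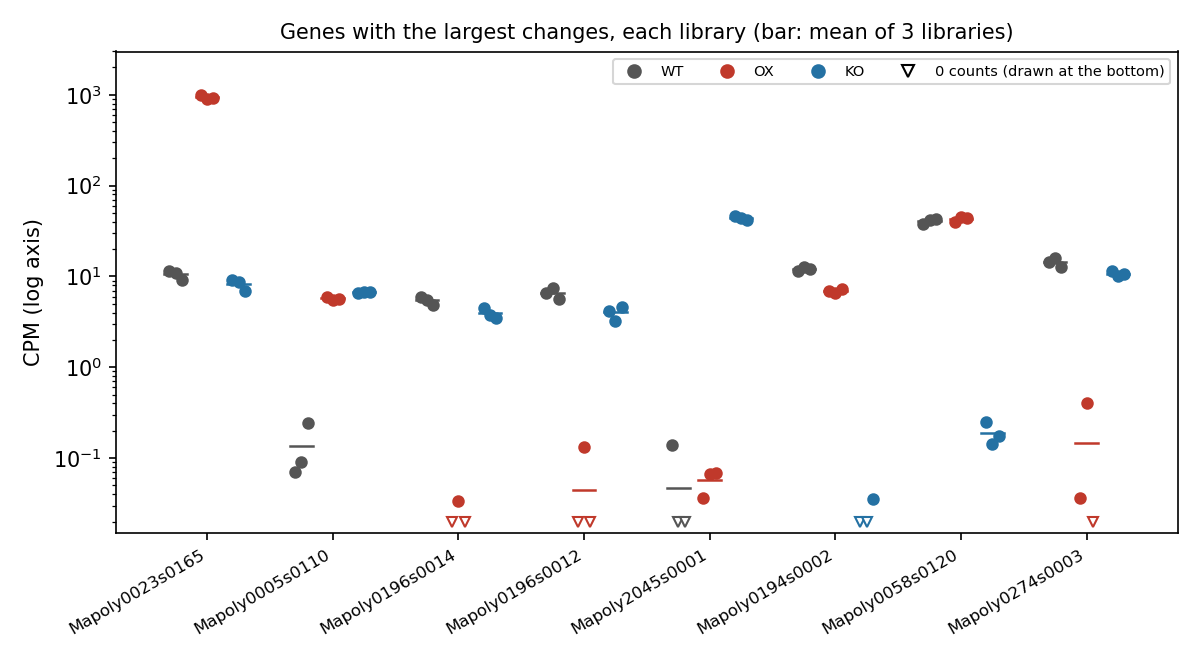
CPM on a log axis of the 8 genes named by the rule of largest change, with 1 point per library, coloured by genotype, and a bar for the mean of 3 libraries where it lies above the bottom of the plot. Open triangles mark libraries with 0 counts; Mapoly0023s0165 has 944 CPM in OX and 10.5 CPM in WT, and Mapoly2045s0001 has 43.9 CPM in KO and at most 0.141 CPM in any library of WT or OX.

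The comparison of KO with WT asks which transcripts differ when the genotype labelled KO is set against the same wild type. The largest rise was that of Mapoly2045s0001, from 0.047 ± 0.081 CPM in WT to 43.9 ± 2.13 CPM in KO (n = 3 libraries each, log2 fold change 9.70 ± 0.31, adjusted p = 2.93e-08). It had 3696 pairs in KO and 4 in WT, all 4 in WT replicate 1, and the ratio of the sums was 854, with a 95% counting interval of 333 to 3135. It had 0.057 ± 0.018 CPM in OX. Among genes with at least 5 CPM in KO, the second largest rise was again that of Mapoly0005s0110, which reached 6.71 ± 0.059 CPM in KO (log2 fold change 5.58 ± 0.26, adjusted p = 3.22e-07). This gene thus rose in both OX and KO, and its levels there did not pass the test against each other (log2 fold change -0.23 ± 0.17, adjusted p = 0.322). The largest fall was that of Mapoly0194s0002, from 12.04 ± 0.66 CPM in WT to 1 read pair in the 3 KO libraries together, against 951 pairs in WT. The ratio of the sums was 1029, with a 95% counting interval of 184 to 40691 (adjusted p = 1.93e-08). In OX it fell less, to 6.87 ± 0.35 CPM (log2 fold change -0.81 ± 0.14, adjusted p = 0.00157). Mapoly0058s0120 fell from 41.2 ± 2.75 to 0.19 ± 0.053 CPM in KO (log2 fold change -7.74 ± 0.13, adjusted p = 3.58e-10). In OX it had 43.0 ± 2.64 CPM, which did not pass the test against WT (adjusted p = 0.579).

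Between KO and WT, 2096 genes (14.1%) changed, 964 of them higher and 1132 lower in KO. With TMM factors 46.0% of the changed genes were higher in KO, and with library size alone 37.5% were. At 2-fold or more, 201 genes rose and 270 fell, and at 16-fold or more 21 rose and 17 fell. The genes that fell at least 4-fold had a median WT level of 1.35 CPM and those that rose as much 0.190 CPM. Part of this gap again follows from the choice by fold change against WT. The libraries of KO and WT did not overlap in 31.2% of genes, against 10% by chance. The number of changed genes was 1293 without KO replicate 2, of which 1266 were among the 2096. With the replicate number as a block, 3516 genes were called, of which 2093 were among the 2096.

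The comparison of OX with KO sets these genotypes against each other directly, and the WT libraries enter only through the scaling, the filter and the shared estimate of the spread. Among genes with at least 5 CPM in the higher genotype, the largest differences were in genes already described from KO. Mapoly0194s0002 had 595 pairs in OX and 1 in KO, a ratio of 611 with a 95% counting interval of 109 to 24161 (adjusted p = 1.72e-08). Mapoly0058s0120 was higher in OX by 7.81 ± 0.13 on the log2 scale (n = 3 libraries each, adjusted p = 1.37e-10). Mapoly2045s0001 was lower in OX, with a log2 fold change of -9.52 ± 0.30 (adjusted p = 9.23e-09). With the same minimum, the second largest fall was that of Mapoly0274s0003, which had 0.146 ± 0.22 CPM in OX and 10.7 ± 0.63 CPM in KO (log2 fold change -6.14 ± 0.48, adjusted p = 5.88e-06). In WT this gene had 14.4 ± 1.65 CPM, and it fell by 6.57 ± 0.48 on the log2 scale from WT to OX (adjusted p = 5.77e-06). Of its counts in OX, 24 were in replicate 2, 2 in replicate 1 and 0 in replicate 3.

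Between OX and KO, 5144 genes (34.7%) changed, 2318 of them higher and 2826 lower in OX. At 2-fold or more, 474 genes were higher and 782 lower in OX. With TMM factors 45.1% of the changed genes were higher in OX, and with library size alone 62.7% were. At 2-fold or more, lower genes outnumbered higher ones with library size alone as well (700 against 536). The libraries did not overlap in 49.1% of genes, against 10% by chance.

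A set of 1068 genes changed in both OX and KO against WT. Of these, 213 rose in both, as Mapoly0005s0110 did, 372 fell in both, as Mapoly0194s0002 did, and 483 went in opposite directions. In the last group 259 genes rose in OX and fell in KO, and 224 fell in OX and rose in KO. This division depended on the scaling and the model. With library size alone it was 339 and 147, and with the replicate number as a block it was 436 and 481. Independent lists of the same sizes would share 519 genes, 101 rising in both, 161 falling in both and 256 opposite. Simulated unchanged groups gave 0 genes called in both in each of 20 simulations. With no gene changed hardly any call arises, so this cannot show how the shared WT libraries affect the overlap of changed genes. Independent lists treat all genes as equally likely to be called, and genes in opposite directions exceeded them as well. With changes of at least 2-fold in both comparisons, 49 genes rose in both, 72 fell in both and 49 were opposite, against 3.09, 12.6 and 13.5 for independent lists. Part of the excess in the same direction may come from the shared WT libraries, which could not be split. Without WT replicate 2, the shared set held 648 genes, 315 of them opposite, and without KO replicate 2 it held 683.

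Across 11850 genes, which leaves out the 2963 of lowest abundance, the 2 sets of fold changes correlated at 0.146, where simulated unchanged groups gave a mean of 0.498 from the shared libraries alone. These 2 correlations cannot be compared directly, since real changes add to the spread of the observed fold changes. The covariance was 0.0307, against 0.00912 in the simulations, a difference of 0.0215. The simulated covariance may be too high, since the simulated counts were noisier than the real ones. The sign was the same in 51.8% of these genes. No such share was computed for the simulations, where the shared WT libraries would also favour the same sign. The correlation, the covariance and this share are values across genes, which are not independent replicates.

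**Figure D3:**
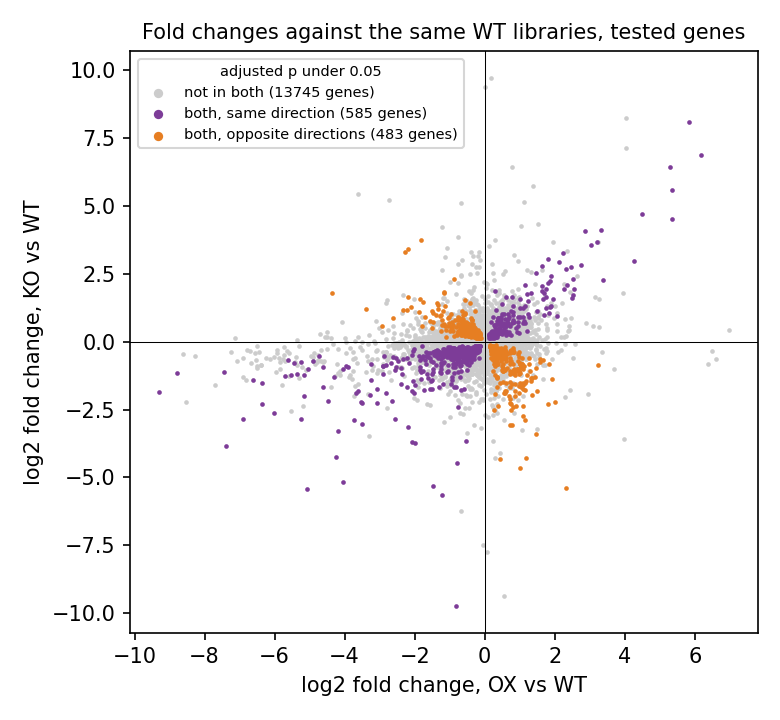
Log2 fold changes of 14813 genes in KO against WT (vertical axis) and OX against WT (horizontal axis), both against the same 3 WT libraries. Purple points mark genes past the threshold in both in the same direction, orange points the 483 genes in opposite directions and grey points all others.

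Genes with Y-chromosome IDs, a list fixed as a marker of the male genome, numbered 113 in the file, of which 34 passed the low-count filter. All but 1 of these 34 had counts in the male plants of all 3 genotypes. Of the 34 tested, 4 rose and 2 fell in OX against WT, and 28 did not pass the test; adjusted over the list alone, the counts were also 4 and 2. The largest of these changes were small, as for MapolyY_B0017 (31.2 ± 1.59 CPM in WT, 36.9 ± 2.33 in OX, log2 fold change 0.24 ± 0.058, adjusted p = 0.0129) and MapolyY_B0048 (10.6 ± 0.62 and 8.56 ± 0.28 CPM, log2 fold change -0.31 ± 0.081, adjusted p = 0.0199). With library size alone, 9 rose and 0 fell, so the falls depended on the scaling. In KO against WT, 0 rose and 2 fell, and adjusted over the list alone the counts were also 0 and 2. MapolyY_A0055 had 0 pairs in KO and 1.46 ± 0.28 CPM in WT, at least 41.0-fold higher than the limit of 3 pairs over the 3 KO libraries (adjusted p = 3.59e-05). MapolyY_B0028 fell from 14.4 ± 1.59 to 8.70 ± 1.36 CPM (log2 fold change -0.72 ± 0.12, adjusted p = 0.0026). These Y-chromosome IDs were singled out after their values were seen.

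As a set, the Y-chromosome IDs did not pass limma's camera in OX against WT (adjusted p = 0.0782) or in KO against WT (adjusted p = 0.12); with 1 list per comparison the adjustment changes no value. In OX against KO, 9 were higher, 1 (MapolyY_B0048) was lower and 24 did not pass the test. Adjusted over the list alone, the counts were also 9 and 1. With upper-quartile factors they were 13 and 1, and with library size alone 16 and 0, so the fall of MapolyY_B0048 depended on the scaling. There the set passed limma's camera with the preset correlation (adjusted p = 0.0137) and did not with an estimated correlation (adjusted p = 0.165). With an estimated correlation the adjusted p was 0.298 in OX against WT and 0.359 in KO against WT. The estimated correlations were 0.0659 to 0.0686, above the preset 0.01, and a larger value makes camera stricter. The limma test fry asks whether the genes move on balance in a single direction, without setting them against the other genes as camera does. It gave an adjusted p of 0.0118 for OX against WT, 0.0107 for KO against WT and 3.84e-04 for OX against KO.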

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

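The run on halved counts was chosen after seeing the data. The count of genes changed in opposite directions was planned as part of the genes changed in both comparisons and was listed as a result of its own after seeing the data. All 228 recomputed fold changes of the 12 named results kept their direction and stayed past the threshold. Their size moved most where few pairs were counted, as for Mapoly2045s0001 in KO against WT. Its log2 fold change was 9.70 as reported and 14.2 without WT replicate 1, the only WT library with counts of it. Without OX replicate 2, Mapoly0196s0012 moved from -7.09 to -11.5 in OX against WT, and Mapoly0274s0003 from -6.14 to -9.06 in OX against KO. Without WT replicate 3, Mapoly0005s0110 moved from 5.35 to 6.14 in OX and from 5.58 to 6.36 in KO, each against WT. The numbers of genes changed stayed within 1.5 times of those reported under 3 other scalings, both filters, DESeq2, limma-voom, fits on 2 genotypes and halved counts. DESeq2 left the adjusted p of 15 genes undefined in each comparison. With a minimum change of 2-fold, 920 genes were called for OX against WT, 471 for KO against WT and 1256 for OX against KO. Then 170 were called in both comparisons with WT, 49 of them in opposite directions. At this depth and replication, 53.7% to 68.7% of simulated 1.5-fold changes were recovered, so small changes are called in part. These shares may be too low, because the simulated counts were noisier than the real ones. The number of comparisons in which the Y-chromosome list passed was 1 as reported, 0 without a filter, 2 with limma-voom, 0 with an estimated correlation and 3 with fry. The estimated correlation is larger than the preset, and fry does not compare the list with other genes. The cause of the other moves was not tested. Leaving out 1 library at a time gave 2680 to 3667 genes for OX against WT, 1293 to 2076 for KO against WT and 4063 to 5332 for OX against KO. It gave 4339 to 5724 for any difference, 648 to 1049 for both comparisons, 315 to 418 for opposite directions and 1 to 2 for the list, with 2 without WT replicate 3. The lowest values for KO against WT and OX against KO came without KO replicate 2. Those for OX against WT, both comparisons and opposite directions came without WT replicate 2, the shallowest library; fewer libraries were then in the fit.

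Libraries with the same replicate number share only the number by the labels. Their deviations from the genotype means correlated at 0.0096 to 0.241, above 0.1 in 6 of 9 pairs, against -0.259 to 0.023 for other pairs. Not every library correlated best with its own number in both other genotypes (7 of 9 did). The third principal component, with 7.08% of the variance, also ordered replicates 1 to 3 alike in each genotype. Its scores were 19.77, -3.51 and -21.09 in WT, 14.98, -2.08 and -12.05 in OX, and 17.18, 3.16 and -16.36 in KO. The data thus point to a difference between replicate numbers that the genotypes share, which the design does not state. The main tests leave it out. With the replicate number as a block, 3516 genes were called for KO against WT, 1960 in both comparisons and 917 in opposite directions, of which 436 rose and 481 fell in OX. The blocked counts for OX against WT (5158), OX against KO (6578) and any difference stayed within 1.5 times of those reported.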

Other observations

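The tests on reads of the KO libraries in OX replicate 2 and all 3 tests on genes switched on or off in KO were chosen only after the results were seen; the patterns themselves were noticed in these data. More genes were nearly lost in OX than in KO. Of the genes with at least 1 CPM in WT, 77 fell at least 16-fold in OX, and 14 did so in KO. In the other direction, 8 genes with at least 1 CPM in OX rose at least 16-fold there, and 11 with at least 1 CPM in KO did so in KO. The 77 genes, Mapoly0196s0012, Mapoly0196s0014 and Mapoly0274s0003 among them, had a median level in KO of 60.5% of that in WT. In KO, 22 of them fell, 1 rose and 54 did not pass the test, beside 1132 falls among all 14813 genes.

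Genes changed in the same direction lay next to each other in ID order more often than in random placements. Of 11828 pairs of tested genes with consecutive numbers on a scaffold, 646 were called in the same direction in OX against WT, where 1000 random placements gave a median of 370 and at most 424. In KO against WT there were 264 such pairs, against a median of 120 and at most 154. The placements were not matched on abundance, and reads shared between overlapping genes or near-identical copies were not checked. In the file, 6 genes had at least 5 CPM in 1 library and at least 20 times the level of every other library.

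The transcripts nearly lost in OX were more abundant in OX replicate 2 than in the other OX libraries. The median share of the WT level over the 77 genes was 4.26% in OX replicate 2, 0.457% in replicate 1 and 0.723% in replicate 3, and replicate 2 was the highest of the OX libraries for 60 of the 77. Spill of reads from the KO libraries would need 4.69% of the KO level, and the 3 most abundant genes called in KO against WT with means in WT and OX under 2% of the KO level, mainly Mapoly2045s0001, reached 0.143% in OX replicate 2, with 2 pairs where 65.6 would be needed (upper 95% limit 7.22). The OX mean used to choose these 3 genes includes OX replicate 2. With a level of 4.69% in that library alone, Mapoly2045s0001 and Mapoly0169s0030 would still have had an OX mean under 2%. Mapoly0010s0216 would not, with 0.0236 CPM in OX against 1.26 CPM in KO and 0 counts in OX replicate 2. The rule also left out Mapoly0093s0054, with 0.103 CPM in OX and 2.15 CPM in KO. The choice of the less abundant genes thus leaned on low levels in OX, and the result rests on Mapoly2045s0001. The 3 genes cannot show reads of the WT libraries in OX replicate 2, and such reads were not tested for. Of the explanations considered, 2 stay open and cannot be told apart. Either 2.81% of WT RNA may have been mixed into this library, or genes responding in OX, the lowered ones above all, may have changed less there. Over 1089 genes changed 1.5- to 4-fold in the other OX libraries, the slope of OX replicate 2 was 0.920 (95% bootstrap interval over genes 0.905 to 0.935), a difference of -0.0733 from the lower of the other OX slopes (0.993), and mixing alone would give 0.955. The difference lay in the 784 lowered genes, with a slope of 0.913 against 1.010 and 1.026 in the other OX libraries, where mixing would give 0.946. For the 305 raised genes the slope was 0.942, against 0.941 in OX replicate 1 and 1.049 in OX replicate 3, where mixing would give 0.986. Each slope was taken over genes chosen anew, 1071 for OX replicate 1 and 1040 for OX replicate 3. The means against which these 2 libraries were set include OX replicate 2. Smaller changes in OX replicate 2 would raise their slopes, so the gaps may be overstated. The mixing values are relative to the mean of OX replicates 1 and 3.

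A few genes were on in one of WT and KO and off in the other, with at least 1 CPM against less than 2% of that level. There were 11, of which 6 were off in KO, Mapoly0058s0120, Mapoly0194s0002 and MapolyY_A0055 among them, and 5 were on in KO, Mapoly2045s0001 among them. By the same rule 35 genes were off and 4 on in OX against WT, and 0 of these were among the 11. That 0 depends on the cutoff. Mapoly0171s0018, among the 11, had 0.0233 CPM in WT and 1.06 CPM in OX, slightly above 2%. Mapoly0005s0110, with 0.135 CPM in WT, 5.72 CPM in OX and 6.71 CPM in KO, was slightly above 2% in both comparisons. A single mislabelled library was excluded, since the lowest correlation within WT or KO (0.990) was above the highest between them (0.983). Such a library could not have made this pattern in any case. In all 11 genes, the WT and KO libraries were at least 10-fold apart. A graded response to the dose of one gene, raised in OX and removed in KO, stays open. It would raise the 6 genes off in KO further in OX, where 0 rose, 2 fell and 4 did not pass the test. The altered gene's row was not identified here, so its own level in OX is not known, and the response may be full at the WT dose. The tally also depends on the cutoff. Mapoly0140s0022, slightly above 2%, had 22.0 CPM in WT, 0.521 CPM in KO and 111 CPM in OX. Among genes changed at least 2-fold in both comparisons, 28 fell in KO and rose in OX, and 72 fell in both. The 5 genes on in KO were too close to 0 in WT to fall further, and 1 of them, Mapoly0171s0018, rose in OX as it did in KO (log2 fold change 5.28, adjusted p = 2.91e-05). A background of the KO line other than the altered gene may also set these genes, and it cannot be told apart from the genotype with 1 line each; 8 of the 11 did not pass the test in OX.

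Genes raised in KO lay often on scaffolds with at most 2 gene IDs. Of 290 tested genes on such scaffolds, Mapoly2045s0001 among them, 71 (24.5%) rose in KO, against 6.16% of the other 14489 tested genes, with the 34 Y-chromosome IDs left out. Low abundance of these genes would give as many in sets matched on abundance, where the median was 17 and the highest of 10000 sets 34. In OX, 80 of the 290 fell, above the highest matched set (71). The 31 that fell in KO and the 32 that rose in OX were within the central 95% of the matched sets (14 to 31 and 18 to 36). Reads shared between near-identical copies, and a difference between lines, were not tested and stay open.

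Other splits of the libraries were fitted as the real one was. For the pairwise comparisons only 10 splits exist, too few for a share under 0.05. The real split was the 1 of 10 with as many genes for OX against WT (3667, highest other 0), for KO against WT (2096, highest other 1) and for OX against KO (5144, highest other 0). Chance could be excluded for the genes that differed between any genotypes, where 1 of 100 splits, the real one, gave as many (5453, highest other 2332, from a split that also kept the OX libraries together). For the genes changed in both comparisons with WT, 2 of 100 splits gave at least 1068. The highest other gave 1906, from a split that kept the OX libraries together and used them as the control. For those in opposite directions, 1 of 100 gave at least 483 (highest other 0). The other splits mix genotypes within groups, and only 13 of them called any gene in the test of any difference. They therefore test again whether the genotypes differ. They cannot tell whether 2 lists of changed genes share more than independent lists would. Chance could not be excluded for the Y-chromosome list, where 72 of 100 splits passed in at least 1 comparison (highest other 3).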
